A study of Mus musculus with 24 samples.

How the data were processed

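Regions of mouse brain sections were profiled on the GeoMx digital spatial profiler, an instrument that hybridizes barcoded RNA probes to a section, releases the barcodes of a chosen region with ultraviolet light and counts them by sequencing. Per the labels' protocols, frozen sections of brains fixed by perfusion were used, regions were chosen on sections stained for Tmem119 and Iba-1, and the barcode libraries were read on a NextSeq 2000. The mice were wild type (WT) or carried a conditional knockout labelled MG-cKO or BMM-cKO, and the labels do not spell out these abbreviations. The series title names macrophage Lyn kinase and subarachnoid haemorrhage, and the submitters' design text calls the WT group WT-SAH and describes 4 regions per brain slice. Sham regions that the design text names were not used here.

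The deposited values are signal per probe target, per the file headers 1 row per target and 1 column per region. No file or label records the counting or normalization software. The values of each deposited signal column were whole multiples of a single step, so that at least 99.985% of the values of every region came out within 0.01 of a whole number of tags. The geometric mean over all 19963 deposited targets was equal in the 4 regions of a group but differed between groups, from 105.92 in WT females to 388.2 in BMM-cKO males. The authors' values therefore carried 1 factor per region that was set within each group. Levels as deposited are not comparable between groups for this reason. The 5 further tables of pairs of groups repeated the values of the full table without a difference. A table of 12 columns named only by genotype was not used, because its names match no single sample.

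All 24 regions entered the analysis, 4 in each of 6 groups, with the group taken from the animal group label. The labels tie no region to an animal. The design text reads as if the 4 regions of a group could come from the same slice, so p-values over regions measure the spread between regions and are too small if regions share animals. This holds for every test reported. All male regions were on scan 2 and all female regions on scan 3, so sex and slide cannot be told apart. The region names of males carry a plus sign after TMEM119 and those of females do not. These names do not say whether the choice of regions differed with it. The library names place 12 male regions and 1 WT female region on plate B, and the other 11 female regions on plate C. Replicate numbers follow deposition order and pair nothing. In all 36 pairs of regions within a group, the recovered tags differed by more than sampling noise (chi-square over its degrees of freedom 1.09 to 11.8), and no region was counted as a duplicate.

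Recovered tag totals ranged from 1839154 to 10779960 per region. The median target had 87 to 506 tags, which gives a counting error of 4.45% to 10.7%, and Lyn had 81 to 579 tags. Tags amplified by PCR are not independent molecules if duplicates were kept, so these errors cover counting only. The negative probe, which matches no mouse transcript, lay at 0.894 to 0.997 times the median target. Most targets were thus near background, and 0.902% to 7.99% of the targets of a region lay above 2 times the negative probe. Levels in the text are given as multiples of the negative probe of the same region, as mean ± SD over 4 regions. A ratio near 1 is therefore background, and a fold change of a target near background understates any change of its transcript.

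The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(value + 1), with 1 coefficient per group over all 24 regions and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The filter kept the 9981 of 19962 targets whose mean, after each region was divided by its geometric mean, was above the median target. Each region was then centred on its median log2 value over these targets. Centring had been planned as an alternative to the values as deposited. It was made the main setting after the separate scaling of the groups was seen, a departure from the plan, and the filter was put on the same common scale. Results on the deposited scale are given beside each comparison. Between groups that scale moves the log2 changes of all targets by nearly the same amount, set by the authors' factors. A sign that turns there follows from this shift and is no separate test of direction. Fold changes are on the log2(value + 1) scale, relative to the median tested target. In simulated data for MG-cKO against WT in males, over 9981 targets of which 200 were changed, the procedure recovered 41.8% of changes of 0.3 log2, 91.0% of 0.6 and 98.5% of 1, with 7 false calls among 9781 unchanged targets. The simulated noise was independent between targets and regions, without deviations that many targets of a region share. These rates therefore do not hold for real regions that differ as a whole.

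The comparisons were MG-cKO against WT, BMM-cKO against WT and MG-cKO against BMM-cKO within each sex, males against females within each genotype, and the interaction of each knockout with sex. For each, 33 gene lists fixed before the data were examined (647 genes, of which 12 names were not found among the targets) were tested with camera, a competitive gene set test in limma, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison; lists with under 3 tested members got no camera test. Genes were named by a rule set at the same time as the lists. It takes Lyn, the 5 largest rises and 5 largest falls among targets that passed the test and whose groups did not overlap (in an interaction, the groups of either sex, a reading made after the values were seen), and, in the comparisons of a knockout with WT, up to 2 passing members per list with the smallest adjusted p. Further list members may be named with values as examples in order of mean level, and the sex comparisons add the sex-linked lists. Some genes that the rule names are not reported here. The files name targets by gene symbol only and name no genome build, so no coordinates are given. Where symbols belong to families with near-identical copies (Trim43, Vmn1r, Vmn2r and similar), the probe may read several copies. Aif1, which encodes Iba-1, and Tmem119 were used to choose the regions, and their levels are no finding. Both are members of the homeostatic microglia list and were not taken out of its levels and tests.

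The alternatives set at the outset were a pseudocount of 10, no filter, a stricter filter that kept 4991 targets, quantile normalization, only the compared groups in the fit, no intensity trend, the plate as a covariate and leaving out each region in turn. After the data were seen, fits were added on the values as deposited, after scaling all regions to the same geometric mean, on the recovered tags with voom weights, after subtracting the negative probe from 2362 targets over 1.5 times its level (with a floor of 0.1), without 4 regions in which under 2% of targets lay above 2 times the negative probe, without BMM-cKO female regions 1 and 3, and with the region number as a block. Exact permutation tests of 4 against 4 regions are two-sided and cannot go below p = 0.0286. They compare the groups by the mean over the targets of a set in each region. Medians printed beside these p-values are a different measure. Markers of brain areas (striatal, cortical and hypothalamic lists) were written after the leading genes had been seen.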

Results

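The series profiled 24 regions of mouse brain stained for microglia and macrophages, after subarachnoid haemorrhage according to its title and design text. There were 4 regions in each of 6 groups, namely WT, MG-cKO and BMM-cKO males and females. The question stated by the title is whether macrophage Lyn, a Src-family tyrosine kinase of myeloid cells, acts differently in the sexes. Each region gave a signal for 19962 probe targets, from 1839154 to 10779960 recovered barcode tags. The BMM-cKO male regions were the deepest as a group, with 6672788 to 10779960 tags. The share of targets above 2 times the negative probe averaged 6.91% ± 1.78 in MG-cKO females, 4.59% ± 1.14 in BMM-cKO females and 3.2% ± 0.370 in WT females (SD, n = 4 regions each). In males it was 2.32% ± 1.09 in WT, 2.39% ± 1.00 in MG-cKO and 2.24% ± 0.378 in BMM-cKO regions.

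Over all regions, the median member of the neuron list lay at 2.36 times the negative probe, that of homeostatic microglia at 1.19 times and that of infiltrating monocytes and macrophages at 1.03 times. Probes for different genes differ in yield, so these levels show the distance from background and not the content of cells. Of the 24 neuron genes, 16 averaged above 2 times the negative probe, as did 15 of 25 ribosomal protein genes and 3 of 24 homeostatic microglia genes. None of the measured members of the lists for NF-kB and inflammatory cytokines (31 genes), Toll-like receptor signalling (26), interferon response (25) or antigen presentation (19) reached that level.

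Lyn, the targeted gene, was close to background in every group. Its level was 1.02 ± 0.0168 times the negative probe in WT males, 1.02 ± 0.127 in MG-cKO males and 1.15 ± 0.0569 in BMM-cKO males (SD, n = 4 regions). In females it was 1.11 ± 0.0344 in WT, 1.04 ± 0.0409 in MG-cKO and 1.11 ± 0.105 in BMM-cKO regions. The limma test found Lyn lower by a log2 change of -0.23 ± 0.09 (SE) in MG-cKO than in WT females, with adjusted p = 0.0446. This call was lost without the filter (-0.20, adjusted p = 0.0905), with quantile normalization (-0.21, 0.0878) and without MG-cKO female region 4 (-0.20, 0.111). The size of the change moved little in these fits, but on the deposited scale its sign turned, to 0.10. The change was -0.00 ± 0.09 in MG-cKO males (adjusted p = 1), 0.18 ± 0.09 in BMM-cKO males (0.0696) and -0.08 ± 0.09 in BMM-cKO females (0.681). The files do not say whether the Lyn probe lies in the deleted part of the gene, so these values do not check the genotype labels. P-values are too small if regions share animals.

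**Figure D1:**
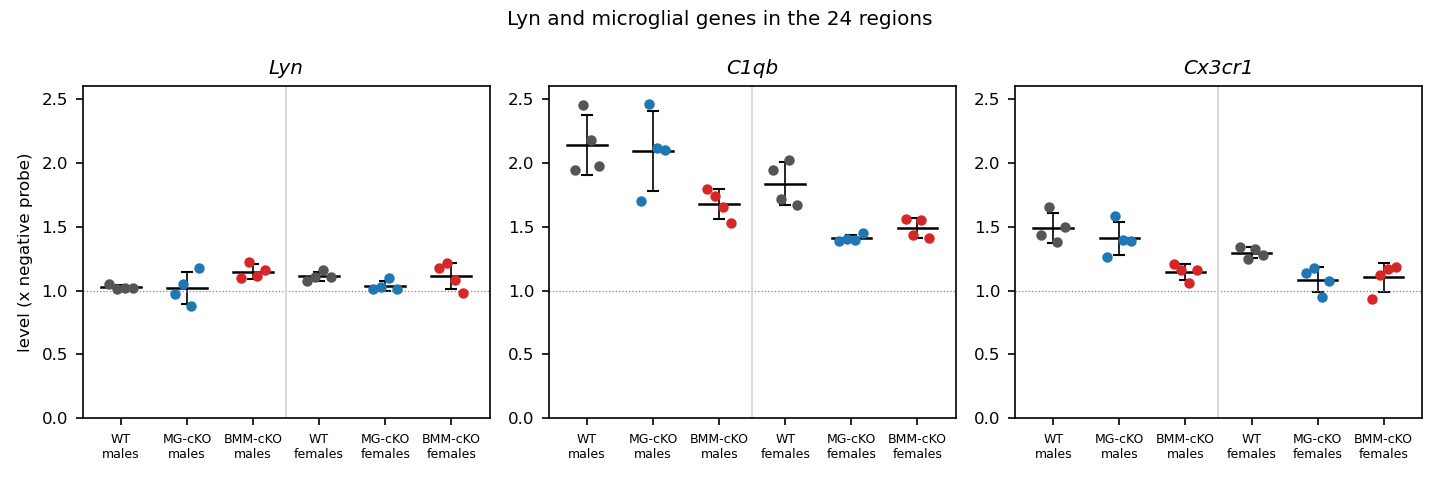
Level of Lyn, C1qb and Cx3cr1 in each region, as multiples of the negative probe of that region (linear axis from 0); points are regions, bars the mean and SD of 4 regions, and the dotted line marks the negative probe. Lyn stayed near 1 in all 6 groups, while C1qb was 1.84 in WT, 1.41 in MG-cKO and 1.49 in BMM-cKO females.

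MG-cKO was compared with WT in males to see which targets differed between these groups. Few targets differed, and the clearest was Pmch, which encodes the precursor of melanin-concentrating hormone, a peptide of lateral hypothalamic neurons. Pmch was 7.14 ± 3.38 times the negative probe in MG-cKO and 0.891 ± 0.0603 times in WT male regions, a 7.44-fold rise (log2 2.89 ± 0.24 SE, limma adjusted p = 6e-09). The 13 hypothalamic markers, listed after the leading genes were seen, had a median log2 change of -0.05 (exact permutation p = 0.229). Whether regions of the 2 groups were placed differently relative to Pmch neurons was not tested, so placement and genotype cannot be told apart for Pmch. Pdyn, the precursor of dynorphin opioid peptides, rose 1.45-fold (adjusted p = 0.0205) and Bmper, a secreted regulator of BMP signalling, 1.38-fold (0.012). The other large rises were Vmn1r198, a vomeronasal receptor, at 1.38-fold and the predicted gene Gm20764 at 1.37-fold. The falls were small, with log2 changes of -0.43 ± 0.10 for Zfp385b, -0.36 ± 0.08 for Dzip1, -0.31 ± 0.07 for the oxysterol-binding protein Osbp and -0.30 ± 0.07 for Zmynd12.

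Gene lists hardly moved in this comparison. Bcl2, the inhibitor of apoptosis, rose by 0.36 ± 0.08 and was the only listed gene past the test (1 of 11 tested members of the cell death list). All 24 tested neuron genes, 19 homeostatic microglia genes, 14 genes of disease-associated microglia, 10 haem and iron genes and 26 oxidative phosphorylation genes stayed short of it. Adjusted over the list alone, 2 cell death genes and 1 gene each of the homeostatic microglia, NF-kB, interferon and blood lists passed as higher, and 1 NF-kB and 1 endothelial gene as lower. No list passed camera. Of 9981 targets, 44 were higher and 4 lower in MG-cKO male regions, and 1498 had an unadjusted p under 0.05. This count is not stable, and of the genes named here only Pmch kept its call whichever region was left out. Without the filter none of the falls named here passed (adjusted p = 0.0772 to 0.106). Without WT male region 3 a single target remained called, without MG-cKO male region 1 the count was 319, and only 8 passed when the 2 groups were fitted alone. On the deposited scale, where the median target lay 0.32 higher, 8039 targets were higher and 0 lower, and Osbp and Zmynd12 had no fall. Quantile normalization gave 97 higher and 36 lower. P-values over regions are too small if regions share animals.

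The largest rises in MG-cKO over WT females included neuronal genes. Nrgn, a calmodulin-binding protein of forebrain excitatory neurons, was 23 ± 7.63 times the negative probe in MG-cKO and 2.28 ± 0.605 times in WT female regions, a 9.11-fold rise (log2 3.19 ± 0.23 SE, limma adjusted p = 2.59e-11). Slc17a7, the vesicular glutamate transporter of cortical and hippocampal neurons, rose 5.59-fold, and the synaptic fusion protein Snap25 5.16-fold. Falls were led by genes abundant in striatal neurons. Ppp1r1b, which encodes DARPP-32, fell from 4.84 ± 2.15 to 1.36 ± 0.212 times the negative probe (3.58-fold, adjusted p = 0.00134). The opioid precursor Penk was 3.27-fold lower, the G protein subunit Gng7 3.05-fold, the imprinted gene Nnat 3.02-fold and the adenylyl cyclase Adcy5 2.25-fold lower.

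Of the 24 tested neuron genes, 19 rose and 1 fell, with a median log2 change of 1.13. In the synapse and activity list 9 of 13 rose, including syntaxin Stx1a by 1.28 ± 0.13. Energy metabolism genes were higher as well. In the oxidative phosphorylation list 23 of 26 rose (Cox5a by 0.99 ± 0.12, Sdha by 0.79 ± 0.11), and in the glycolysis and hypoxia list 12 of 20 rose and 1 fell (2 adjusted over the list alone), with Pkm higher by 1.21 ± 0.19 and Gpi1 by 0.86 ± 0.14. The chaperones Hsp90aa1 (1.17 ± 0.16) and Hspa8 (1.03 ± 0.18) were among 6 of 15 heat shock genes that rose. Of 24 ribosomal protein genes 7 rose, among them Rplp0 by 0.48 ± 0.09. Of 15 astrocyte genes 7 rose, including the glutamate transporter Slc1a2 by 1.10 ± 0.18 and Aldoc by 0.97 ± 0.20. With quantile normalization Slc1a2 (0.22, adjusted p = 0.276) and Aldoc (0.37, 0.108) did not pass. The preset camera test called these lists higher, with adjusted p = 2.47e-12 for neurons and 3.09e-12 for oxidative phosphorylation. With an estimated correlation neither list nor any other passed in this comparison (adjusted p = 0.2 for neurons, 0.371 for oxidative phosphorylation, 0.2 for the synapse list, 0.442 for glycolysis, 0.505 for astrocytes and for heat shock, and 0.581 for ribosomal proteins).

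Microglial genes moved the other way. Of 19 tested homeostatic microglia genes 11 fell and none rose, with a median of -0.35 (camera adjusted p = 2.72e-05, and 0.204 with an estimated correlation). The lysosomal protease Ctss fell by 0.56 on the log2 scale (SE 0.10), C1qb by 0.50 (SE 0.09), C1qc by 0.46 (SE 0.10) and the lipid receptor Trem2 by 0.38 (SE 0.08). C1qb and C1qc were also among 3 of 9 complement genes that fell (camera adjusted p = 0.0464, and 0.486 with an estimated correlation). In the disease-associated microglia list 3 of 14 rose, including the cathepsin Ctsb (0.81 ± 0.16) and Ank (0.58 ± 0.08), which neurons express as well. In the Src-family and inhibitory-receptor list 2 rose and 5 of 15 fell, with Sirpa, a receptor also abundant on neurons, at 0.61 ± 0.12; adjusted over the list alone, 6 fell. Of 7 tested interferon genes 2 fell, among them Ifit3 (-0.33 ± 0.08). Col6a1, a collagen of meningeal fibroblasts, was lower by a log2 change of -0.60 ± 0.09. Among blood genes the haemoglobin gene Hba-a1 rose 4.48-fold, to 4.02 ± 2.35 times the negative probe from 0.648 ± 0.0447. Its 4 MG-cKO female regions ranged from 0.844 to 6.373. Gpx4, which protects lipids from peroxidation, was the riser of the haem and iron list (0.55 ± 0.16) and the ferrireductase Steap3 its faller (-0.24 ± 0.08), with the other 8 tested members not passing. Steap3 lost its call without the filter (adjusted p = 0.0938), with the 2 groups fitted alone (0.0513) and without WT female region 3 (0.14), and Gpx4 without WT female region 4 (0.0511). Of the 6 tested Toll-like receptor genes 0 passed. MG-cKO female region 2 had a lower share of targets above 2 times the negative probe (4.25%) than the other MG-cKO female regions (7.64% to 7.99%).

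In total 1787 targets were higher and 1190 lower in MG-cKO females, with 146 higher and 6 lower by more than 2-fold. P-values over regions are too small if regions share animals. On the deposited scale, where the median target lay 0.30 higher, 7066 targets were higher and 18 lower. Falls under about 0.3, such as those of Lyn and Steap3, turn into rises there, and those of C1qb, C1qc, Ctss and the striatal genes do not. With the negative probe subtracted, 1139 of 2362 targets passed.

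**Figure D2:**
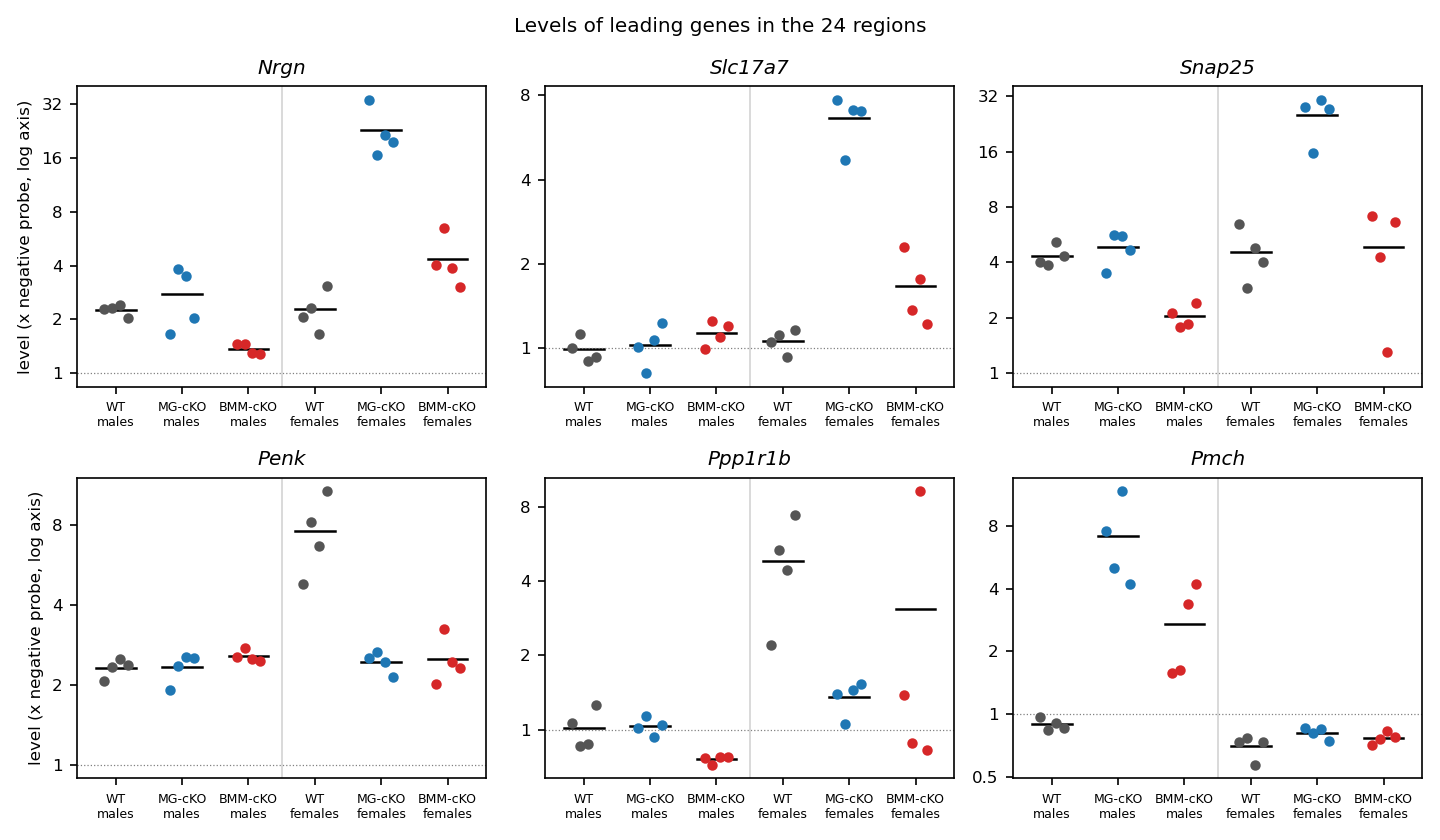
Level of 6 leading genes in each region, as multiples of the negative probe of that region on a log axis; points are regions, bars the mean of 4 regions, and the dotted line marks the negative probe. Nrgn, Slc17a7 and Snap25 stood out in MG-cKO females, Penk and Ppp1r1b in WT females, and Pmch in MG-cKO and BMM-cKO males; Ppp1r1b also reached 9.238 in BMM-cKO female region 3.

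In males, BMM-cKO against WT gave the most calls, and abundant neuronal and housekeeping genes were lower. Ndn, an imprinted neuronal gene, was 1.67 ± 0.395 times the negative probe in BMM-cKO and 4.53 ± 1.54 times in WT male regions, a 2.6-fold fall (log2 -1.38 ± 0.33 SE, limma adjusted p = 0.00108). Snap25 was 2.10-fold lower (0.00828), the neuronal surface protein Thy1 2.08-fold (0.000337), Ndrg4 2.03-fold (0.00118) and the glycolytic enzyme Aldoa 2.01-fold (0.000166). Without low-signal regions Snap25 did not pass (log2 -1.10, adjusted p = 0.0591), although its fall was of similar size. Pmch rose 2.79-fold, to 2.70 ± 1.31 from 0.891 ± 0.0603 times the negative probe. The other large rises were of genes under 1.5 times the negative probe in WT males, namely Trim43b (2.14-fold), the vesicle-tethering protein Vps54 (1.94-fold), the nuclear envelope protein Lemd2 (1.93-fold) and the RNA pseudouridine synthase Trub2 (1.93-fold). On the deposited scale, where the median target lay 1.49 higher, all falls named for this comparison turn into rises, as falls smaller than that shift must.

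Lists of highly expressed genes fell together. Of 24 ribosomal protein genes 20 fell and none rose (median -0.43), with Rplp0 lower by a log2 change of -0.52 ± 0.09. In oxidative phosphorylation 20 of 26 fell and 1 rose (Cox7a2 -0.65 ± 0.11, Ndufb9 -0.62 ± 0.09). Of the 24 neuron genes 15 fell (17 adjusted over the list alone), including the glutamate receptor subunit Grin1 (-0.73 ± 0.18), as did 6 of 13 synapse genes, with the postsynaptic scaffold Dlg4 at -0.83 ± 0.15 and the activity-induced factor Npas4 at -0.72 ± 0.09. Camera called these 4 lists lower (adjusted p = 1.16e-05, 5.71e-05, 0.00487 and 0.0231 in that order), and with an estimated correlation each had adjusted p = 0.699. Other members fell without a call for their list, as in oligodendrocytes (6 of 14, Olig1 -0.60 ± 0.17), astrocytes (4 of 15, 1 adjusted over the list alone, S100b -0.51 ± 0.11) and glycolysis (10 of 20 lower and 4 higher, 11 lower adjusted over the list alone, Gpi1 -0.91 ± 0.14).

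Myeloid and inflammatory lists split. Of 19 homeostatic microglia genes 10 fell and 3 rose, including the purinergic receptor P2ry13 at -0.56 ± 0.09, with C1qc at -0.39 ± 0.10 and C1qb at -0.32 ± 0.09. In the Src-family list 6 rose and 1 of 15 fell, with the adaptor Dok1 at 0.66 ± 0.09. Of 7 tested interferon genes 5 rose and 1 fell, among them Ifit3 (0.48 ± 0.08) and the nucleic acid sensor Zbp1 (0.55 ± 0.10). In the cell death list 6 of 11 rose and 1 fell, with the inflammasome protease Casp1 at 0.52 ± 0.08 and Bcl2l1 at 0.53 ± 0.08. The Toll-like receptor adaptor Traf6 rose by 0.94 ± 0.10 while Irf5 fell by 0.37 on the log2 scale (SE 0.08). In phagocytosis genes 6 rose (7 adjusted over the list alone) and 6 fell of 17, for example the integrin Itgb3 (0.76 ± 0.09) and the GTPase Rac2 (-0.45 ± 0.09). The neutrophil genes Elane (0.70 ± 0.08) and Il1r2 (0.62 ± 0.09) were 2 of 3 that rose among 5. No myeloid list passed camera (adjusted p = 0.062 for homeostatic microglia, 0.183 for the Src-family list). Most of 1192 probes for receptors and keratin-associated proteins that brain is not known to use changed by between -0.483 and 0.56 in this comparison. The rest of these probes lay beyond that range. The values of Ifit3, Zbp1, Casp1, Bcl2l1, C1qb, C1qc, Irf5 and Rac2 lie within that range, so they cannot be told apart from shifts of probe background. Those of Elane, Il1r2, Dok1, Itgb3, Traf6 and P2ry13 lie beyond it. They are not thereby shown to be more than such shifts, because some of the 1192 probes lay beyond it too.

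Targets that brain regions are not known to use moved as well. Of 1192 probes for olfactory, vomeronasal, trace amine and taste receptors and keratin-associated proteins, 46.9% differed between BMM-cKO and WT males, against 10.4% for MG-cKO against WT females. The share was also 46.5% for males against females in WT and 31.1% in MG-cKO, 28.9% between the knockouts in males and 31.1% for the BMM-cKO interaction with sex. In the remaining comparisons it was 0.0839% to 10.2%. These shares come from a fit of all 19962 targets and not from the main fit. Without the filter, 8871 of 19962 targets were called in BMM-cKO against WT males and 3120 in MG-cKO against WT females. In BMM-cKO males the share of the 1192 probes was thus close to that over all targets. All 4 tested Y-linked genes were higher in BMM-cKO than in WT males, including Uty by 0.50 ± 0.07 and Usp9y by 0.40 ± 0.10, although both groups are male. The spread of the non-brain probes (SD of log2 level) was 0.317 ± 0.0229 in WT and 0.313 ± 0.0335 in MG-cKO males, against 0.396 ± 0.0155 in BMM-cKO males and 0.384 to 0.405 as means of the female groups. In total 2779 targets were higher and 2568 lower, of which 2 and 5 by more than 2-fold. As deposited, 9966 were higher and 0 lower. With the negative probe subtracted, 765 of 2362 targets were higher and 892 lower. P-values over regions are too small if regions share animals.

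BMM-cKO females differed from WT females in fewer targets, led by striatal genes that were lower. Penk was 2.5 ± 0.521 times the negative probe in BMM-cKO and 7.62 ± 2.53 times in WT female regions, a 3.11-fold fall (log2 -1.64 ± 0.16 SE, limma adjusted p = 6.41e-07). Gng7 was 2.75-fold lower, Arpp21, a cAMP-regulated phosphoprotein of striatal neurons, 2.57-fold, the actin regulator Phactr1 2.24-fold and the thyroid hormone-binding protein Crym 2.14-fold. Gnas, the stimulatory G protein subunit, rose 3.07-fold, to 12.6 ± 5.00 from 4.00 ± 1.86 times the negative probe (adjusted p = 0.00276). The neurite growth gene Nrn1 rose 2.08-fold, clusterin (Clu) 1.91-fold, Nrbp2 1.81-fold and the metalloproteinase inhibitor Timp2 1.76-fold.

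The GABA neuron genes Gad2 (-1.06 ± 0.26) and Slc32a1 (-0.95 ± 0.24) were 2 of 3 neuron genes that fell, while 2 of 24 rose (3 adjusted over the list alone). Complexin Cplx2 was the synapse gene that fell (-0.62 ± 0.16), and 2 did when adjusted over the list alone. Of 19 homeostatic microglia genes 2 fell (3 adjusted over the list alone), C1qb by 0.37 on the log2 scale (SE 0.09) and the fractalkine receptor Cx3cr1 by 0.31 (SE 0.08). In the disease-associated list Timp2 and the protease Ctsl (0.44 ± 0.12) rose, and 3 genes did when adjusted over the list alone. Single members rose in astrocytes (Aldh1l1, 0.45 ± 0.10), haem and iron handling (Gpx4, 0.60 ± 0.16), ribosomal proteins (Rplp0, 0.33 ± 0.09), oxidative phosphorylation (Sdha, 0.44 ± 0.11) and chaperones (Canx, 0.58 ± 0.14), and 2 in glycolysis (Gpi1 0.64 ± 0.14, Hk1 0.41 ± 0.11). Adjusted over the list alone, 5 astrocyte and 4 heat shock genes rose. Col6a1 (-0.52 ± 0.09) and the immunoproteasome subunit Psmb9 (-0.31 ± 0.07) were lower. Camera called homeostatic microglia lower (adjusted p = 0.000189, median -0.22) and 6 lists higher, and with an estimated correlation none passed (0.632 for homeostatic microglia, 0.794 for oxidative phosphorylation, 0.812 for ribosomal proteins, 0.716 for heat shock, 0.411 for disease-associated microglia, 0.718 for glycolysis and 0.812 for astrocytes). None of the tested members of the Src-family list (15), interferon response (7), NF-kB list (6) or Toll-like receptor list (6) passed; in the last, 1 was higher and 1 lower when adjusted over the list alone.

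BMM-cKO female regions 1 and 3 had leading genes of their own. The transthyretin gene Ttr, the main product of choroid plexus, was at 361.1 times the negative probe in region 3 and at 1.060 to 1.353 in the others. Gfap, the astrocyte filament gene, was 5.747 in region 1 and 1.124 to 1.862 in the others. The totals were 135 targets higher and 99 lower. Without regions 1 and 3 they were 378 and 110, and these named genes no longer passed: Clu (0.39, adjusted p = 0.13), Gpx4 (0.27, 0.165), Aldh1l1 (0.32, 0.0647), Gad2 (-0.61, 0.193), Slc32a1 (-0.60, 0.195), Cx3cr1 (-0.25, 0.151), Ctsl (0.23, 0.207), Rplp0 (0.23, 0.192) and Sdha (0.36, 0.11). With the plate as a covariate, WT female region 1 in effect drops out of this comparison, because no other female region was on plate B. That fit also ended the calls of Gad2 (-0.99, adjusted p = 0.0563), Slc32a1 (-0.82, 0.0852), Cx3cr1 (-0.30, 0.0642), Ctsl (0.44, 0.0642) and Rplp0 (0.30, 0.0889). The size of these changes moved little. Without the filter, Cx3cr1, Ctsl, Psmb9, Gpx4, Cplx2, Rplp0, Sdha and Hk1 did not pass (adjusted p = 0.0561 to 0.0878), and with voom Ctsl, Gpx4, Rplp0, Sdha, Hk1 and Canx did not (0.0598 to 0.119). Leaving out a single region ended the calls of C1qb (WT region 3, 0.0667), Cx3cr1 (BMM-cKO region 1, 0.102), Psmb9 (BMM-cKO region 2, 0.0853), Ctsl, Gpx4, Rplp0 and Sdha (BMM-cKO region 3, 0.11, 0.0693, 0.12 and 0.0704), and Slc32a1, Cplx2 and Hk1 (BMM-cKO region 4, 0.0953, 0.14 and 0.143). Without WT female region 2 the count was 60. With the compared groups fitted alone it was 11, and of the genes named here only Penk, Gng7, Phactr1 and Crym passed (0.0258 each). The others lost their calls, with adjusted p from 0.0562 for Nrbp2 to 0.32 for Gpx4, among them Gnas (0.128), Nrn1 (0.155), Clu (0.266), Timp2 (0.102), Arpp21 (0.138), C1qb (0.138), Col6a1 (0.147) and Psmb9 (0.211). Scaling to equal geometric means gave 92 higher and 107 lower. On the deposited scale, with a median shift of 0.64, 9910 were higher and 7 lower. There C1qb, Cx3cr1, Psmb9, Cplx2 and Col6a1 change sign, and Penk, Gng7, Arpp21, Phactr1 and Crym stay lower. P-values are too small if regions share animals. Both female comparisons use the same WT regions, so falls of the same genes in both are not independent.

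**Figure D3:**
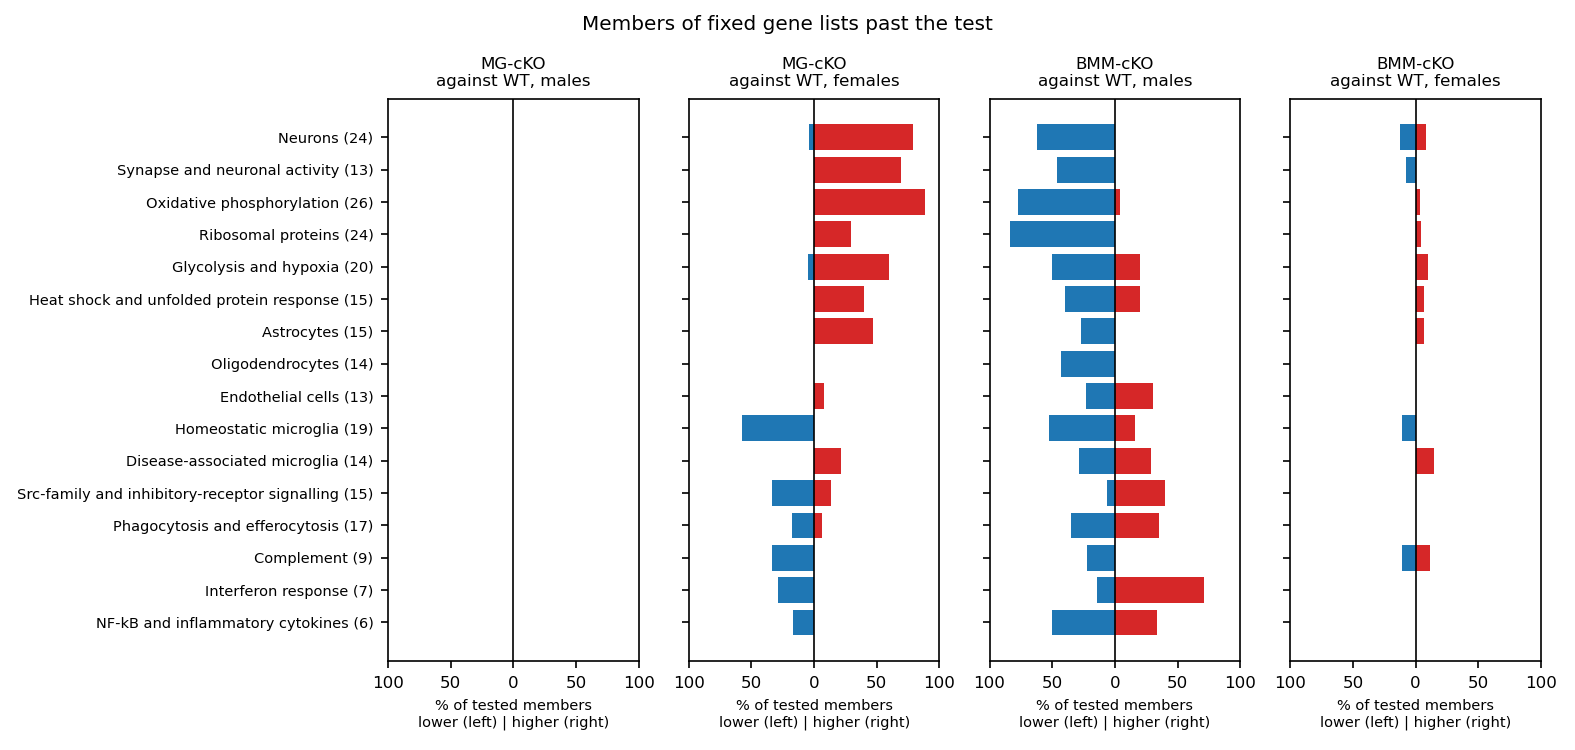
Share of tested members (number in brackets) of 16 fixed gene lists that passed the test as higher (right, red) or lower (left, blue) in each comparison of a knockout with WT, relative to the median target. In MG-cKO females 19 of 24 neuron genes rose and 11 of 19 homeostatic microglia genes fell, and in BMM-cKO males 20 of 24 ribosomal protein genes fell. On the deposited scale, which shifts all targets of that comparison upwards, the falls in BMM-cKO males turn into rises.

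The knockouts were also compared with each other. In males, the largest rises of MG-cKO over BMM-cKO regions were Snap25, 2.33-fold higher (log2 1.22 ± 0.33 SE, limma adjusted p = 0.00524), the neuronal protein Ncdn 2.12-fold, Thy1 2.08-fold, the pentraxin Nptx1 1.98-fold and Aldoa 1.98-fold. Lower in MG-cKO were Wnt2b (1.69-fold), Vps54 (1.63-fold), Trim43a (1.63-fold), Wnt9a (1.62-fold) and the tRNA-modifying enzyme Trmu (1.62-fold), all under 1.5 times the negative probe in MG-cKO males. Lyn did not pass (-0.18 ± 0.09, adjusted p = 0.0877). In total 1809 targets were higher and 2035 lower, against 1319 and 2419 after scaling to equal geometric means. As deposited, with a median shift of -1.18, 0 were higher and 9924 lower, and Ncdn, Thy1, Nptx1 and Aldoa change sign. Ribosomal protein genes were higher in 21 of 24 cases (camera adjusted p = 2.81e-07, and 0.6 with an estimated correlation). Neuron genes were higher in 9 of 24 cases and synapse genes in 3 of 13 (adjusted p = 0.6 for both with an estimated correlation).

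In females, MG-cKO regions exceeded BMM-cKO regions in Snap25 (5.87-fold, log2 2.55 ± 0.33 SE, limma adjusted p = 1.6e-06), complexin Cplx1 (5.59-fold), Nrgn (5.08-fold), Slc17a7 (3.88-fold) and the secreted Wnt modulator Dkk3 (3.82-fold). Lower were Zic1, a transcription factor of septal, thalamic and cerebellar neurons (2.04-fold), Timp2 (1.82-fold), Timp3 (1.75-fold), Wdr6 (1.73-fold) and angiotensinogen, Agt (1.71-fold). Of 13 tested synapse genes 10 were higher, and this list passed camera with the estimated correlation too (adjusted p = 0.0161). For neurons 19 of 24 were higher (adjusted p = 0.0614 with an estimated correlation). Lyn did not pass (-0.15 ± 0.09, adjusted p = 0.269). The preset test also called oxidative phosphorylation (12 of 26) and glycolysis (7 of 20) higher, and ependyma and choroid plexus (median -0.53, adjusted p = 0.0219), fibroblasts and meninges (-0.19, 0.0196) and homeostatic microglia (-0.13, 0.0219) lower. With an estimated correlation these had adjusted p = 0.525, and 0.387 for fibroblasts. Cortical markers moved with the synapse list (median 0.64, 10 of 13 passing as higher, exact p = 0.0286), so brain area is not separable from it. In total 1100 targets were higher and 353 lower, and 549 and 62 with these groups fitted alone, where Timp3 did not pass (adjusted p = 0.104). As deposited, with a median shift of -0.33, the split was 386 higher and 7443 lower, and the named genes kept their direction. These p-values, like those between the knockouts in males, are too small if regions share animals.

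Males were compared with females within each genotype, with sex and slide inseparable. Markers of brain areas differed as well. Hypothalamic markers (13, listed after the leading genes were seen) had a median log2 change of 0.36 in WT, 0.30 in MG-cKO and 0.12 in BMM-cKO regions, each with exact p = 0.0286, with 7, 6 and 2 passing as higher and 2, 0 and 0 as lower. Cortical markers had -0.61 in MG-cKO regions (10 of 13 passing as lower, 1 as higher, exact p = 0.0286). The choice of brain area is therefore not separable from sex either. In WT regions, Sparc, a matricellular protein, was 3.80-fold higher in males (5.97 ± 1.83 against 1.68 ± 0.840 times the negative probe, log2 1.92 ± 0.29 SE, limma adjusted p = 1.54e-05), Gnas 2.48-fold, Ndn 2.34-fold, Nnat 2.15-fold and Tmem130 2.04-fold. The largest falls were of Ppp1r1b, 4.34-fold lower in males, Arpp21 3.62-fold, Penk 3.11-fold, the dendritic protein gene Ddn 2.58-fold and Gng7 2.27-fold lower. The Y-linked genes Uty (1.26 ± 0.115 against 1.61 ± 0.0480 times the negative probe, adjusted p = 0.000315) and Zfy2 (adjusted p = 0.0123) passed as lower in males, against the labelled sex, and turn to 0.01 and 0.07 on the deposited scale. Zfy2 did not pass without WT female region 1 (adjusted p = 0.0518) or with the negative probe subtracted (0.0903), and Nnat not without WT male region 3 (0.0792) or with the subtraction (0.0516). Without the filter, the Y-linked gene Kdm5d was higher in males (log2 0.43 ± 0.11, adjusted p = 0.00274) and Ddx3y was not different (0.02 ± 0.10, 0.895). Eif2s3y was higher (0.23, adjusted p = 0.0383), and Usp9y (-0.30, 0.0262) and Sry (-0.32, 0.00273) were lower. In the knockouts Ddx3y (0.46, adjusted p = 0.000731, in MG-cKO and 0.43, 0.00363, in BMM-cKO) and Eif2s3y (0.25, 0.0364, and 0.42, 0.00153) were higher in males, as were Zfy1 in MG-cKO (0.28, 0.0413) and Kdm5d in BMM-cKO (0.40, 0.0212), and Sry was lower in MG-cKO males (-0.23, 0.0412). At these levels the Y-linked probes do not separate the labelled sexes in WT regions. In total 1626 targets were higher and 2317 lower, 969 and 3074 with equal geometric means, and 6779 and 256 as deposited (median shift 0.34). With the plate as a covariate this comparison in effect set the male regions against WT female region 1 alone, the only female region on plate B. The log2 changes of that fit thus rest on 1 female region. Of the large rises and falls named here, Nnat (1.25) had no smaller change there. The others had smaller changes, such as Sparc at 1.08, Ppp1r1b at -1.09, Arpp21 at -0.92 and Penk at -1.01. Of 19 homeostatic microglia genes 11 were higher and 1 lower in WT males (median 0.23, camera adjusted p = 0.0111, and 0.979 with an estimated correlation).

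In MG-cKO regions, Pmch was 8.97-fold higher in males (log2 3.16 ± 0.24 SE, limma adjusted p = 6.57e-11) and Hcrt, the orexin precursor, 6.33-fold. Hcrt was 17.95 times the negative probe in MG-cKO male region 4 and 0.655 in region 2. Nnat was 6.66-fold, Sparc 4.85-fold and Hap1 2.5-fold higher. Lower in males were Nrgn (7.63-fold), Slc17a7 (5.71-fold), Camk2n1 (5.38-fold), Cplx1 (4.80-fold) and Snap25 (4.63-fold). Homeostatic microglia genes were higher in males for 15 of 19 members (median 0.42), and synapse genes lower for 10 of 13, both also with the estimated correlation (adjusted p = 0.0244 and 0.0267). The microglia list holds Aif1 and Tmem119, which were used to choose the regions. The region names give the Tmem119 stain differently for the sexes, so region choice is not separable from sex here. In total 605 targets were higher and 1363 lower. Equal geometric means gave 281 and 1940, quantile normalization 590 and 726, and the deposited scale 7116 and 422 (median shift 0.32). With the plate as a covariate 110 and 464 passed, without Hcrt (2.95, main 2.66), Hap1 (1.28, main 1.32) and Sparc (1.15, main 2.28). The losses of Hcrt and Hap1 came with little change in size. The plate estimate rests on 1 WT female region on plate B, so this fit cannot decide about a plate effect in MG-cKO or BMM-cKO regions.

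In BMM-cKO regions Pmch was 3.45-fold higher in males (log2 1.79 ± 0.24 SE, limma adjusted p = 1.87e-05), followed by Tmem202 (1.44-fold), Vmn2r19 (1.40-fold), the chemokine Xcl1 (1.40-fold) and Tmprss11c (1.36-fold). Lower in males were the predicted gene Gm52800 (3.14-fold), the amyloid precursor App (2.87-fold), Nrgn (2.82-fold), Slc22a17 (2.61-fold) and the sodium pump subunit Atp1b1 (2.59-fold). Homeostatic microglia genes were higher for 4 of 19 members (camera adjusted p = 0.00227, and 0.451 with an estimated correlation). Oxidative phosphorylation genes were lower for 19 of 26 members (camera adjusted p = 3.94e-13, and 0.451 with an estimated correlation). The totals were 565 higher and 1117 lower, 979 and 1063 with quantile normalization, 59 and 708 with voom on the recovered tags, and 9894 and 0 as deposited (median shift 1.22). With the plate as a covariate 81 and 240 passed, without Tmem202 (0.44), Xcl1 (0.51), Gm52800 (-1.77), Nrgn (-1.32) and Slc22a17 (-1.63), whose main values were 0.52, 0.48, -1.65, -1.49 and -1.38. With voom Vmn2r19 (adjusted p = 0.0551), Xcl1 (0.176) and Tmprss11c (0.0518) did not pass, and Xcl1 did not without BMM-cKO female region 1 (0.0975). Lyn did not differ past the threshold between the sexes in WT (-0.10 ± 0.09, adjusted p = 0.346), MG-cKO (0.12 ± 0.09, 0.33) or BMM-cKO regions (0.16 ± 0.09, 0.191). P-values of all sex comparisons are too small if regions share animals.

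The interaction asked whether the difference of a knockout from WT was unlike in the sexes. A positive value means a higher log2 change in males than in females. For MG-cKO, the interaction of Pmch, which rose in males, was 2.80 ± 0.34 (SE, limma adjusted p = 1.3e-06). Those of Ppp1r1b (1.89), Penk (1.72), Nnat (1.63) and Gng7 (1.47) were positive because these genes fell in MG-cKO females. Those of Nrgn (-2.97 ± 0.33, 2.99e-07), Slc17a7 (-2.42), Snap25 (-2.22) and Hba-a1 (-2.14, adjusted p = 0.0331), which rose in MG-cKO females, were negative. Hba-a1 lost its call with quantile normalization (-1.76, adjusted p = 0.0868), with the negative probe subtracted (-3.36, 0.154) and without WT male region 1 (-1.73, 0.0822). Nnat lost it without low-signal regions (1.42, 0.0994) and without WT female region 3 (1.46, 0.0548). Of the 24 neuron genes 18 passed as negative, as did 20 of 26 oxidative phosphorylation genes, and 8 of 19 homeostatic microglia genes passed as positive. With an estimated correlation these lists had adjusted p = 0.274, 0.645 and 0.645. In total 1280 targets had a positive and 1422 a negative interaction, and 1062 and 1473 as deposited (median shift -0.0065). Lyn did not pass (0.23 ± 0.12, adjusted p = 0.164).

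For BMM-cKO, the positive interactions were led by Penk (1.80 ± 0.23 SE, limma adjusted p = 2.77e-06), Arpp21 (1.5), Pmch (1.42), Crym (1.35) and Hikeshi, a nuclear import carrier of heat shock proteins (1.21). The negative ones were led by Ttr (-3.29 ± 1.36, adjusted p = 0.0486), the prostaglandin D synthase Ptgds (-2.47 ± 0.62), Gnas (-2.46 ± 0.42), Npcd (-2.11 ± 0.63) and Ndn (-1.77 ± 0.47). Most of the Ttr value came from the BMM-cKO female region at 361.1 times the negative probe, without which it was -1.23 and passed (adjusted p = 0.00308). With all regions the call was lost with a pseudocount of 10 (0.0516), the stricter filter (0.0524), equal geometric means (0.0525), no trend (0.0575), the plate (0.0616) and the compared groups alone (0.11), and also without low-signal regions (0.159). Ribosomal protein genes passed as negative in 21 of 24 cases and oxidative phosphorylation genes in 20 of 26 (adjusted p = 0.735 for both with an estimated correlation). In total 2418 targets had a positive and 2143 a negative interaction, and 8954 and 16 as deposited (median shift 0.86). Lyn did not pass (0.26 ± 0.12, adjusted p = 0.0749). Because all males and all females were on separate slides and p-values over regions are too small if regions share animals, both interactions hold slide and region choice as well as sex.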

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

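The tests of explanations in this part were chosen after the result was seen; the interaction tests and their random splits were not. In groups of 4 regions, the region furthest from the others was compared with the spread of its group for the list levels, the share of targets above background and the levels of the named genes. Of 371 groups 26 held a region that stood apart, and chance gives about 1 in 20, which is 19.

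MG-cKO female region 2 had the lower signal over background: 4.25% of targets above 2 times the negative probe (others 7.64% to 7.99%), and log2 levels over the negative probe of 1.72 for neurons (2.29 to 2.37), 1.11 for ribosomal proteins (1.38 to 1.41) and 0.50 for heat shock genes (0.81 to 0.83). MG-cKO male region 1 was low in ribosomal proteins (0.75, others 1.18 to 1.26), heat shock genes (0.19, others 0.46 to 0.50) and Nnat (3.90 times the negative probe, others 7.02 to 7.15). BMM-cKO female region 3 was high in ependyma and choroid plexus genes (2.15, others 0.07 to 0.11), phagocytosis genes (0.36, others 0.20 to 0.21) and Clu (11.7 times, others 3.46 to 4.85). BMM-cKO female region 1 was high in oligodendrocyte genes (1.02, others 0.03 to 0.17) and blood genes (0.0046, others -0.28 to -0.25) and low in X-linked genes that escape inactivation (0.025, others 0.15 to 0.18). MG-cKO male region 4 stood apart in border-associated macrophage genes (-0.051, others -0.00 to 0.00), pericyte genes (0.093, others 0.00 to 0.02) and Zmynd12 (1.49 times, others 1.2 to 1.22), region 2 in antigen presentation (-0.10, others -0.16 to -0.15) and region 3 in alternative activation (-0.19, others -0.12 to -0.11). In MG-cKO females, region 3 stood apart in Lyn (1.10 times, others 1.01 to 1.03) and Gng7 (0.696 times, others 0.893 to 0.928), and region 1 in Nnat (1.29 times, others 0.902 to 0.967). In WT females these were region 1 in pericyte genes (0.10, others 0.02 to 0.03), region 2 in Hba-a1 (0.714 times, others 0.618 to 0.634) and region 4 in lymphocyte genes (-0.13, others -0.08). The remaining ones were WT male region 3 in Ndrg4 (4.87 times, others 3.58 to 3.79) and BMM-cKO female region 4 in Timp2 (3.70 times, others 2.24 to 2.40).

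The difference of a knockout from WT was unlike in the sexes by the interaction test for 2702 targets with MG-cKO and 4561 with BMM-cKO, with sex and slide inseparable. The named log2 interactions were, for MG-cKO, Pmch 2.80, Ppp1r1b 1.89, Penk 1.72, Nnat 1.63, Gng7 1.47, Nrgn -2.97, Slc17a7 -2.42, Snap25 -2.22 and Hba-a1 -2.14. For BMM-cKO they were Penk 1.80, Arpp21 1.5, Pmch 1.42, Crym 1.35, Hikeshi 1.21, Ttr -3.29, Ptgds -2.47, Gnas -2.46, Npcd -2.11 and Ndn -1.77. Among 100 random splits, 1, the real one, gave as many targets for MG-cKO (highest other 2302) and 1 for BMM-cKO (highest other 3676). The real split thus ranked first for both counts over all regions, which makes chance less likely but does not exclude it. With single regions left out, the MG-cKO count fell to as low as 2164 (without WT female region 4), under the highest other split. The BMM-cKO count stayed at 4068 or more. The splits were not repeated with a region left out.

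Cortical genes rose and striatal genes fell in MG-cKO against WT females, among them Nrgn, Slc17a7, Ppp1r1b and Penk of the interactions above. A candidate explanation is that the regions of these groups lay in different brain areas. Cortical markers outside the named genes (13 of 15) had a median log2 change of 0.63 and striatal markers (14) of -0.31, each with exact p = 0.0286, the smallest that 4 against 4 regions can give. Hypothalamic markers (13) had a median of -0.18. As deposited the medians were 0.95, 0.012 and 0.15. The striatal markers were also lower than in WT in BMM-cKO females (median -0.33, 14 of 14 lower, 0.31 as deposited) and males (-0.28, 12 of 14 lower, 1.22 as deposited), each with exact p = 0.0286. Cortical medians there were -0.0092 (exact p = 0.571) and -0.0089 (0.0286), where the p-values test the mean over markers and not the median. Both female comparisons share the WT regions, so their falls are not independent. Against a higher signal over background as the whole source, the 19 tested members of the microglia list fell by 0.16 over the negative probe, and all 24 measured members by 0.12 (exact p = 0.0286 for both). The fall of this list had been seen before the test was chosen. Most other lists were higher over the negative probe in MG-cKO than in WT females, such as complement (0.092 against 0.065) and antigen presentation (-0.16 against -0.25). Neutrophil (0.019 against 0.047) and ependyma genes (0.082 against 0.087) were lower. A higher signal as part of the source stays open. Against an effect of the genotype in both sexes, the cortical markers in males had a median of -0.065 (exact p = 0.343, range -0.14 to 0.18). An effect of MG-cKO in females alone was not separable from the choice of regions.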

How the results depend on the processing

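The fits on the deposited scale, equal geometric means, voom, subtraction, the region-number block and the 2 fits without regions in doubt were chosen after the data were seen. The edgeR and DESeq2 tests set for whole counts were not run, because the deposited unit is not a count. Counts of targets called that moved by more than 1.5 times are given here, with the main count first; where no reason is given, the cause was not tested. MG-cKO against WT in males (48) gave 25 with the stricter filter, 133 with quantile normalization, 8 with only the compared groups, 93 with voom, 94 with the negative probe subtracted, 85 without low-signal regions, and 29 with the replicate block. As deposited, where a shift between separately scaled groups enters every target, the counts were 8039 (MG-cKO males) and 7084 (MG-cKO females, main 2977) against WT, 9966 (BMM-cKO males, 5347) and 9917 (BMM-cKO females, 234), 9924 and 7829 for MG-cKO against BMM-cKO in males (3844) and females (1453), 7035, 7538 and 9894 for the sexes in WT (3943), MG-cKO (1968) and BMM-cKO (1682), and 8970 for the BMM-cKO interaction (4561). With the negative probe subtracted, which left 2362 targets, they were 1139 and 1657 for MG-cKO females and BMM-cKO males against WT, 1406 and 467 between the knockouts in males and females, 1266, 565 and 912 for the sexes in the same order, and 1031 and 1520 for the interactions (MG-cKO main 2702). Without the filter, BMM-cKO against WT gave 8871 in males and 150 in females, and the sexes 6975 in WT and 3596 in MG-cKO. The stricter filter gave 3031 for BMM-cKO males, 2343 between the knockouts in males, 2233 and 1311 for the sexes in WT and MG-cKO, and 2711 for the BMM-cKO interaction. With only the compared groups, BMM-cKO females gave 11 and the knockouts in females 611; quantile normalization gave 911 for the latter. The plate left 1222, 574 and 321 for the sexes in WT, MG-cKO and BMM-cKO, an estimate that rests on 1 WT female region on plate B, and voom left 767 in BMM-cKO. Without low-signal regions the knockouts in males gave 2522 and the sexes in MG-cKO 1309, with fewer regions; without BMM-cKO female regions 1 and 3, BMM-cKO females gave 488. Gene lists called fell from 60 to 3 with an estimated correlation.

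Leaving out each region in turn gave 1 to 319 for MG-cKO males against WT (5, 2 and 4 without MG-cKO regions 2, 3 and 4, and 88, 24 and 3 without WT regions 1, 2 and 4), 2256 to 3479 for MG-cKO females, 4787 to 5161 for BMM-cKO males and 60 to 362 for BMM-cKO females (60, 152 and 68 without WT regions 2, 3 and 4, and 362 without BMM-cKO region 3). Between the knockouts it gave 3060 to 3537 in males and 1020 to 1954 in females, for the sexes 3196 to 3828 in WT, 1449 to 2315 in MG-cKO and 997 to 1845 in BMM-cKO (1073 and 997 without BMM-cKO male regions 1 and 3), and for the interactions 2164 to 3228 and 4068 to 4670. The replicate block uses numbers in deposition order, which pair nothing. Deviations of same-numbered regions had a mean correlation of 0.01 (-0.24 to 0.24), 8 of 24 regions correlated best with their own number, and the block moved no other count by more than 1.5 times. For the named genes, leaving aside the deposited scale, 2863 values kept direction and side of the threshold, 198 lost and 10 gained a call, and 3 changed sign, all of Lyn in MG-cKO against WT males, from -0.00 to 0.012 without the filter, 0.046 without low-signal regions and 0.080 without MG-cKO male region 3 (-0.064 without region 4). Of the fits that left out a region, these counts hold only those with the lowest and the highest fold change of each gene. Calls lost in other such fits are not counted. On the deposited scale 62 of 232 named values changed sign, 32 of them in BMM-cKO against WT males. Signal over background limits all of this, since 0.902% to 7.99% of targets lay above 2 times the negative probe.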

Other observations

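The tests in this part were chosen after the result was seen, except the thinning of the BMM-cKO male libraries and the splits of the regions. For each comparison the 8 regions were split in all 35 ways into groups of 4. For MG-cKO against WT in males 2 of the 35 splits gave as many targets as the real 48 (highest other 90), so chance cannot be excluded there. For the other comparisons 1 split, the real one, gave as many. That is a share of 0.0286, the smallest that 35 splits allow, and it was not adjusted for the number of comparisons. It makes chance a less likely source of the counts over all regions but does not exclude it. The real count and the highest other were 2977 and 1403 for MG-cKO against WT in females, 5347 and 0 for BMM-cKO in males, and 234 and 155 for BMM-cKO in females. They were 3844 and 1 between the knockouts in males and 1453 and 1113 in females, and 3943 and 126, 1968 and 717, and 1682 and 7 for the sexes in WT, MG-cKO and BMM-cKO. The count for BMM-cKO females was 60, 152 and 68 without WT regions 2, 3 and 4 and 11 with the compared groups alone. That between the knockouts in females was 1099, 1020 and 1048 without MG-cKO regions 1, 3 and 4 and 611 alone. All of these lie under the highest other split, and the counts moved with single regions and with the fit. The splits were not repeated with a region left out or with the groups alone, so chance was not tested there. These splits treat regions as units and say nothing about animals.

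BMM-cKO against WT males shifted targets in both directions, including probes for receptors and keratin-associated proteins that brain is not known to use. A flatter probe background in WT male regions may account for part of this, since the fold changes of the 1192 probes followed the background profile of the female regions (correlation 0.495, rank correlation 0.414). Of the comparisons without female regions, the correlation was -0.514 between the knockouts in males and 0.268 for MG-cKO against WT in males. The pattern is thus not confined to one comparison, although these share male regions with it. For males against females it was -0.596 in WT, -0.621 in MG-cKO and 0.035 in BMM-cKO. It was 0.285 in the MG-cKO and 0.485 in the BMM-cKO interaction. The sex comparisons and interactions use female regions that make up the profile, so a correlation is partly built in and they decide nothing. The smaller counting error of deeper libraries does not account for the calls. After the BMM-cKO male regions were thinned to the WT male median depth, 5272 targets were called, against 5344 before. Thinning leaves the make-up of a library unchanged, so a background that changes with depth was not tested.

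The fall of neuron, ribosomal and oxidative phosphorylation genes in the same comparison runs against a flatter background in WT males as its cause, since that would make these genes look lower in WT males. The 74 tested members had a median log2 difference over the negative probe of -0.53 in BMM-cKO males (70 lower, exact p = 0.0286, the smallest that 4 against 4 regions can give). These are the genes in which the fall was seen, so the value speaks to its direction alone. The test was first run on the 907 targets over 2 times the negative probe in females, where it was undecided (median -0.21, exact p = 0.143). Of these 907 targets 64.6% were lower over the negative probe, which leaves a lower signal over background in BMM-cKO males open; it cannot be told apart from an effect of the genotype.

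Lyn was not clearly lower in the knockout groups. A candidate explanation is that its signal lay within the probe background, since in WT regions Lyn (1.07 times the negative probe) was at percentile 73.5 of the 1192 probes for genes that brain is not known to use. RNA of other cells in the regions was not tested. The test does not show whether Lyn was deleted in the cells of interest.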
